A study of Homo sapiens with 6 samples.

How the data were processed

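RNA of SaOS2 cells, a human osteosarcoma line with osteoblast features, was compared between cultures given atorvastatin and untreated cultures at 6, 15 and 24 hours. Atorvastatin is a statin, a class of drugs that inhibit the mevalonate pathway, which supplies cholesterol and the lipid anchors of prenylated proteins. Each of the 6 two-colour arrays carried atorvastatin RNA in one dye and untreated RNA of the same time in the other, per the labels, with 2 biological replicates per time according to the series description. On the replicate 1 arrays the atorvastatin RNA was labelled with Cy5 and on the replicate 2 arrays with Cy3, so that replicate number and dye orientation coincide. If the ratios are all turned to atorvastatin over untreated, a dye effect cancels in the mean of each time, but it enters the spread between the 2 replicates. Dose and vehicle were not given in the sources used here.

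The values are the deposited log ratios, taken here as log2, of 27648 spots per array with no missing value. Their log base, the image analysis, the background correction and the normalization are not given in the sources used here. Base 10 was excluded because the highest value, 8.62, would exceed the range of a 16-bit scanner, whereas natural logarithms were not excluded. Sizes and folds below hold only if the base is 2. Medians of the 6 deposited columns were -0.0114 and 0.0151 at 6 h, -0.0048 and 0.0142 at 15 h, and -0.0067 and 0.0089 at 24 h for replicates 1 and 2. The arrays had therefore been centred or normalized before deposit.

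The direction of the ratios is also not stated. The rules on direction, lists, tests and named genes were fixed before the data were examined. The direction rule used the genes of cholesterol synthesis and uptake, which statins raise in textbook knowledge. After centring, their median was 0.12 and 0.14 at 6 h, 0.12 and 0.24 at 15 h, and -0.045 and 0.10 at 24 h on the replicate 1 and replicate 2 arrays. It was above 0 on 5 of the 6 arrays, of both dye orientations, so the values were taken as atorvastatin over untreated on all arrays, and this direction is called likely only. The cholesterol list is for that reason no independent evidence of its own direction. Over all genes, arrays of the same dye orientation correlated with r between 0.42 and 0.72, and arrays of opposite orientation with r between -0.63 and -0.42. With the sign of the replicate 2 arrays turned instead, 5457 genes would differ for the mean of the 3 times and no gene list would, a reading tried after the data were examined.

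Of the 27648 rows, 17711 had 1 gene symbol, 0 had several and 9937 had none in the platform annotation. Symbols were updated through the RefSeq gene table of GRCh38.p14: 14718 rows by accession, 1816 by current symbol and 1085 by older symbol, while 92 kept the name given. Rows of one gene were averaged, which gave 14533 genes, 2067 of them with more than 1 row. No genome build is named for the array, so no coordinates are given. One of the gene lists and some genes are not reported here. The precision is limited by the number of arrays. Spot intensities were not analysed here, so signal over background is unknown.

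Each array was centred on its median over genes. One linear model with a coefficient per time was fitted to all 6 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a term for the replicate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts were the ratio at each time, the mean of the 3 times, 24 h against 6 h, and any difference between times (moderated F). Gene lists, 24 in number, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists within each comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Camera with an estimated correlation takes its degrees of freedom from the few residual ones of the fit. Few lists can therefore pass it, even where the estimated correlation is low. With the preset correlation the p-value rests on the spread between genes. It does not measure how far a list varies between arrays, however small it is. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 prepared the table, and matplotlib 3.10.9 drew the plots.

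The replicate numbers paired the arrays: after subtraction of the time means, the deviations of same-numbered arrays correlated at 0.71 between 6 h and 15 h, 0.76 between 6 h and 24 h, and 0.70 between 15 h and 24 h, which may be dye orientation or culture. A fit with the replicate number as a block was therefore set beside the fit without it. The block term itself passed the threshold for 5551 of 14533 genes (38.2%), and the median residual SD was 0.26 without it and 0.131 with it. Residual degrees of freedom were 3 without and 2 with the block.

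Both fits were tested on simulated arrays that had the measured replicate term and spread and 50 changed genes of each size among 14533. For the mean of the 3 times, the fit without the block recovered 2.0% of genes changed by 0.5 on the log2 scale, 72.0% of those changed by 1 and 96.0% of those changed by 2. The block recovered 94.0% and 100.0% of genes changed by 0.5 and by 1, and called 13 to 20 unchanged genes per comparison against 0 without it. At 24 h alone, changes of 1 were recovered in 2.0% of genes without the block and changes of 2 in 64.0%. For 24 h against 6 h, no simulated change up to 2 was recovered without the block. The adjustment is stricter where fewer genes change, so these rates and counts need not hold for the measured table. At 24 h the block recovered 100% of simulated changes of 1. In the measured table ACTA2 at -2.16 and CCN1 at -1.61 had adjusted p of 0.153 and 0.154 there (limma with the block). In a simulated table with one list of 20 genes lowered by 0.4, that list passed camera, and 6 of 200 random unchanged lists had p under 0.05. The simulated noise was independent between genes. It cannot show that list p-values hold where genes correlate, as in the cholesterol list, with an estimated correlation of 0.149 without the block.

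Genes are named by a fixed rule. For each time and for the mean, the rule took the 8 largest rises and the 8 largest falls among genes past the threshold with one sign on every array used, and 5 in each direction for 24 h against 6 h. From each list it took the 4 members with the smallest p in the comparison described. Genes outside the rule are said to be chosen after their values were seen. Other settings tried were values not centred, arrays scaled to one median absolute value, quantile normalization, rows tested separately, a robust prior, array weights, a floor of 1 on the log2 ratio, and each array left out in turn. One array, replicate 1 at 24 h, bears a different date from the others, a batch of 1 array that the fit without it covers. The replicate 1 array at 6 h has a title number apart from those of the other arrays, and whether this marks a batch is not stated. Both arrays enter the comparison of 24 h against 6 h.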

Results

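In all, 6 two-colour arrays compared atorvastatin-treated with untreated SaOS2 osteosarcoma cells, 2 at each of 6, 15 and 24 hours, with 14533 genes measured on every array. The study's description gives the comparison of treated with untreated cells at the 3 times as its design. Values are log2 ratios of atorvastatin over untreated, a direction that is likely but not stated, with the SD between the 2 replicates of a time. The replicates had opposite dye orientation, so this SD holds any dye effect. ACTB, with 321 spots, and GAPDH, with 272 spots, gave within-array spot SDs of 0.13 to 0.27 and 0.13 to 0.21 on the log2 scale.

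At 6 h, genes of cholesterol synthesis and uptake and genes of heat shock and oxidative stress ranked above other genes. Targets of SRF and its coactivator MRTF ranked below other genes. These calls held with the preset correlation and not with an estimated one, and by fry only the heat shock list passed (adjusted p = 0.0106). The cholesterol list had a median log2 ratio of 0.13, with 16 of 22 measured members above 0 (limma camera, adjusted p = 0.000459, or adjusted p = 0.704 with an estimated correlation). Its members with the smallest p were HSD17B7 at 0.24 ± 0.134 (SD, n = 2), ACAT2 at 0.25 ± 0.191, LSS at 0.20 ± 0.123 and STARD4 at 0.20 ± 0.105, none past the test adjusted over the list alone. This list set the direction of all ratios and is not independent evidence for it. The 13 measured genes of heat shock and oxidative stress had a median of 0.23 (adjusted p = 1.12e-06, or adjusted p = 0.238 with an estimated correlation). Among them MT2A, which encodes a metal-binding metallothionein, rose by a log2 ratio of 1.70 ± 0.332 (3.25-fold), with adjusted p = 0.00361 over the list alone by limma. TXNRD1 stood at 0.42 ± 0.584, HSPB1 at 0.33 ± 0.382 and HSPH1 at 0.30 ± 0.084 without passing.

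The SRF and MRTF list, which holds actins and other contractile and adhesion genes, had a median of -0.08 at 6 h with 16 of 19 members below 0 (camera, adjusted p = 0.000333, or adjusted p = 0.238 with an estimated correlation). The list's median was below 0 on both 6 h arrays, as those of the cholesterol and heat shock lists were above 0 on both. FHL2 stood at -0.46 ± 0.127, SRF at -0.59 ± 0.010, ACTA2 at -0.46 ± 0.526 and ACTB at -0.20 ± 0.168. Targets of YAP and TEAD, transcription regulators that respond to the actin cytoskeleton, had a median of -0.03 and a mean of -0.08, with 12 of 22 below 0 (camera, adjusted p = 0.0401, or adjusted p = 0.704 with an estimated correlation). CCN1, a secreted matrix protein, stood at -0.99 ± 0.066, CCN2 at -0.39 ± 0.007, AMOTL2 at -0.30 ± 0.307 and GADD45B at -0.28 ± 0.172. With the replicate block, the YAP and TEAD list was past the threshold no longer (adjusted p = 0.216), and CCN1 passed over its list alone (limma, adjusted p = 0.0195). That list's median was 0.08 on the replicate 1 array and -0.15 on the replicate 2 array. No gene passed over all genes in limma, with 47 at an unadjusted p under 0.05 and 600 with the block. By chance a share of 0.05 of the 14533 genes would have such a p, more than either count. The same holds without the block for every comparison below. With the block it holds for 24 h against 6 h and for any difference between times, while the counts at 15 h, 24 h and for the mean exceed that share. The 6 h calls also rested on single arrays. Without replicate 2 the adjusted p was 0.928 for cholesterol, 0.619 for SRF, 0.068 for heat shock and 1 for YAP, and without replicate 1 it was 0.0518 for SRF and 0.0524 for YAP.

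At 15 h the SRF and MRTF list was lower than at 6 h by value, with a median of -0.43 and 17 of 19 members below 0 (camera, adjusted p = 1.05e-17). ACTG1, a cytoplasmic actin, fell by 1.33 on the log2 scale (2.51-fold, SD 0.320, n = 2), ACTA2, smooth muscle actin, fell by 1.48 (SD 0.131) and FHL2, a LIM-domain protein, fell by 0.94 (SD 0.424). These 3 passed the test adjusted over the list alone, with limma values of 0.00602, 0.0203 and 0.0203, and 11 members passed with the replicate block. ACTB stood at -0.43 ± 0.024 and passed only with the block. The list's median was below 0 on both 15 h arrays. The call was lost with an estimated correlation (adjusted p = 0.0557 with an estimated correlation, and 0.366 with the block as well). That estimate, -0.024 without the block, lay below the preset 0.01. By fry the list passed (adjusted p = 0.0255, and 0.0379 with the block).

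YAP and TEAD targets were lower as a group at 15 h, with a median of -0.11 and 17 of 22 below 0 (camera, adjusted p = 0.000164, or adjusted p = 0.358 with an estimated correlation). CCN1 fell by 1.36 (SD 0.635, limma, adjusted p = 0.0326 over the list alone). AMOTL2, a regulator of YAP, stood at -0.66 ± 0.133, GADD45B at -0.41 ± 0.025 and IGFBP3 at -0.34 ± 0.354. One member passed over the list alone, and 5 with the block. The medians of the YAP and the cholesterol list had the same sign on both 15 h arrays. The cholesterol list had a median of 0.15 with 15 of 22 members above 0 (camera, adjusted p = 0.000312, or adjusted p = 0.538 with an estimated correlation). MVK, mevalonate kinase, stood at 0.32 ± 0.113 and FDPS, farnesyl diphosphate synthase, at 0.51 ± 0.333. HSD17B7 stood at 0.37 ± 0.003 and SQLE, squalene epoxidase, at 0.57 ± 0.365. None of its members passed over the list alone, and 3 did with the block. Cytoplasmic ribosomal proteins had a median of 0.13 (camera, adjusted p = 0.045, or adjusted p = 0.674 with an estimated correlation), with RPL10 at 0.23 ± 0.125, RPL19 at 0.39 ± 0.314, RPL32 at 0.30 ± 0.337 and RPL30 at 0.18 ± 0.295 (-0.03 without replicate 2). The 2 rows of RPL10 differed in their changes, at 0.17 and 0.47 on replicate 1 and 0.27 and 0.02 on replicate 2, and those of IGFBP3 at 0.11 and -0.30 on replicate 1. The ribosomal median was -0.01 on the replicate 1 array and 0.27 on the replicate 2 array. That call came from one array, since without replicate 2 the list ranked lower instead (adjusted p = 0.825). Without the same array the adjusted p was 0.187 for both the cholesterol and the YAP list. No gene passed over all genes in limma at 15 h, with 145 at an unadjusted p under 0.05 and 1130 with the block. Without replicate 1, whose partner array carries 44 spots above 4, 30 genes passed.

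At 24 h all 19 measured SRF and MRTF targets lay below 0, with a median log2 ratio of -0.55 (camera, adjusted p = 2.76e-31, and adjusted p = 0.0238 with an estimated correlation). With the replicate block and an estimated correlation the call was lost (adjusted p = 0.214). By fry the list passed (adjusted p = 0.00363, and 0.013 with the block). The list's median was -0.51 and -0.64 on the 2 arrays. In limma, 10 members fell over the list alone. ACTA2 fell by 2.16 (4.45-fold, SD 0.714, n = 2), ACTG1 fell by 1.31 (2.49-fold, SD 0.196), TPM1, a tropomyosin of actin filaments, fell by 0.70 (SD 0.088) and ACTB fell by 0.55 (1.46-fold, SD 0.028). Their limma values adjusted over the list alone were 0.00502, 0.00502, 0.0145 and 0.0314. The other 6 were TAGLN, CALD1, ACTN1, FHL2, MYL9 and TPM2, at -0.91 to -0.48, and 13 members passed with the block. The 2 rows of TPM1 differed, with 6-array means of -0.68 and -0.04, as did those of CALD1 at -0.16 and -0.68 (0.07 and -1.07 on the replicate 1 array at 24 h). The plot of the SRF and MRTF genes gives each array's value.

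**Figure D1:**
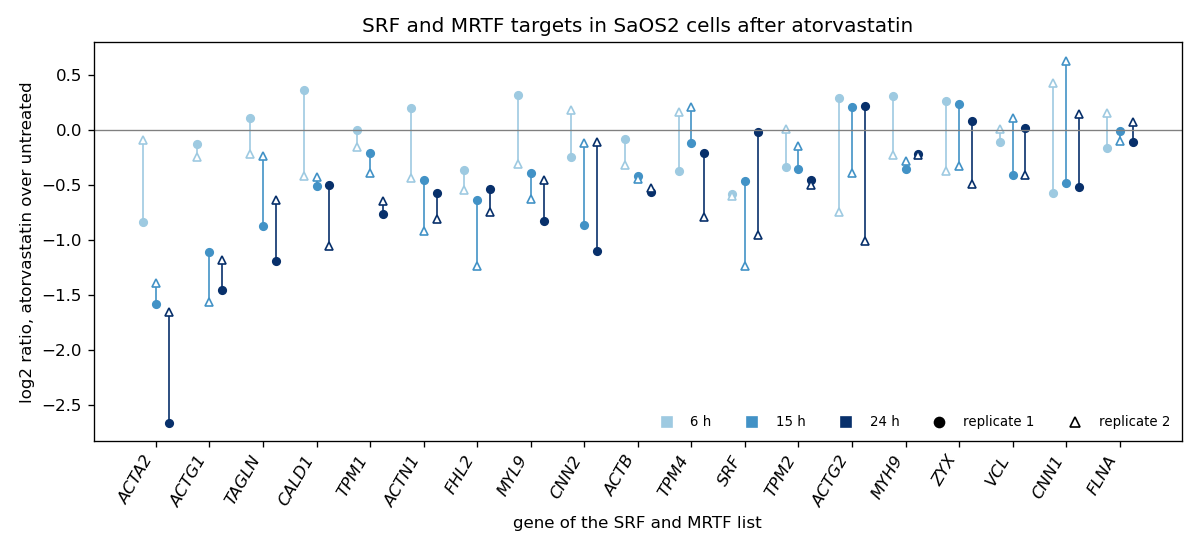
Log2 ratio of atorvastatin over untreated (vertical axis) for the 19 measured SRF and MRTF targets (horizontal axis), ordered by their mean at 24 h; filled circles are replicate 1 arrays, open triangles replicate 2 arrays, and a line joins the 2 arrays of a time. ACTA2 stood at -2.66 and -1.65 at 24 h, and ACTG1 at -1.45 and -1.18.

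YAP and TEAD targets had a median of -0.06 at 24 h with 14 of 22 below 0 (camera, adjusted p = 0.00827, or adjusted p = 0.323 with an estimated correlation). CCN1 fell by 1.61 (SD 0.152, limma, adjusted p = 0.0145 over the list alone). AMOTL2 stood at -0.39 ± 0.263, MYOF at -0.42 ± 0.375 and CCN2 at -0.25 ± 0.420 (0.05 without replicate 2). The list's median was 0.04 on the replicate 1 array and -0.23 on the replicate 2 array, without which the adjusted p was 0.894. Kruppel-like transcription factors had a median of 0.16, with 8 of 9 above 0 and both arrays' medians above 0 (camera, adjusted p = 0.00231, or adjusted p = 0.223 with an estimated correlation). KLF6 stood at 0.79 ± 0.348 and KLF2, an endothelial regulator known to respond to statins, at 1.33 ± 0.658. KLF7 stood at -0.21 ± 0.278 and KLF9 at 0.29 ± 0.059. None passed over the list alone, and 2 did with the replicate block. The heat shock and oxidative stress list had a median of 0.06 and a mean of 0.22, with both arrays' medians above 0 (camera, adjusted p = 0.00022, or adjusted p = 0.223 with an estimated correlation). MT2A rose by a log2 ratio of 1.39 ± 0.128 (2.61-fold) and NQO1, a quinone reductase, by 0.65 ± 0.059 (1.57-fold), with limma values of 0.01 and 0.015 adjusted over the list alone. HMOX1, heme oxygenase, stood at 0.36 ± 0.288 and SRXN1 at 0.26 ± 0.370 (-0.004 without replicate 1). Genes of ER stress and the integrated stress response had a median of 0.08 (camera, adjusted p = 0.00581, or adjusted p = 0.223 with an estimated correlation), which was -0.04 on the replicate 1 array and 0.17 on the replicate 2 array. ASNS, asparagine synthetase, stood at 0.37 ± 0.059, ATF3 at 0.42 ± 0.180, DNAJB9 at 0.32 ± 0.058 and ATF4 at 0.26 ± 0.055, none past the list-alone test. The SD of ATF3 hides rows of opposite sign that cancel within an array, from -0.96 to 1.51 on replicate 1 and from -0.90 to 1.51 on replicate 2. The Kruppel-like list had 0.0571 and 0.25 without replicate 1 and 2 at 24 h, the heat shock list 0.0557 and 0.0971, and the ER stress list 0.0557 and 0.616. No gene passed over all genes in limma, with 154 at an unadjusted p under 0.05 and 984 with the block.

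Over the mean of the 3 times, SRF and MRTF targets fell, with a median of -0.37 and all 19 below 0 (camera, adjusted p = 4.01e-32, and adjusted p = 0.0229 with an estimated correlation). With the block and an estimated correlation the call was lost (adjusted p = 0.214), while by fry the list passed (adjusted p = 0.00382, and 0.0124 with the block). The list's median was below 0 on 6 of 6 arrays. In all, 11 members fell over the list alone in limma, led by ACTG1 at -0.94 ± 0.612 (SD over 6 arrays), ACTA2 at -1.37 ± 0.862, FHL2 at -0.68 ± 0.301 and ACTB at -0.39 ± 0.177, each below 0 on all 6 arrays. For ACTG1 the sign on the replicate 1 array at 6 h came from averaging, since its 2 rows stood at 0.194 and -0.448 there. The YAP and TEAD list had a median of -0.07 with 18 of 22 below 0 and a median below 0 on 4 of 6 arrays (camera, adjusted p = 1.29e-05, or adjusted p = 0.185 with an estimated correlation). CCN1 stood 2.50-fold lower at -1.32 ± 0.405, and it passed over the list alone (limma, adjusted p = 0.00242), and 4 members did with the block. AMOTL2 stood at -0.45 ± 0.254, GADD45B at -0.27 ± 0.155 and CCN2 at -0.25 ± 0.240. The 2 rows of AMOTL2 differed, at -0.82 and -0.08. The YAP and TEAD list had a mean of -0.14 and was not tested without CCN1. How far its calls at each time and for the mean rest on that gene is open.

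The heat shock and oxidative stress list had a median of 0.11 over the 3 times and a median above 0 on 6 of 6 arrays (camera, adjusted p = 1.75e-07, or adjusted p = 0.111 with an estimated correlation). MT2A rose by a log2 ratio of 1.60 ± 0.298 (3.03-fold) and was above 0 on all 6 arrays, and NQO1 rose by 0.32 ± 0.282, with limma values of 0.000283 and 0.0289 adjusted over the list alone. HMOX1 stood at 0.28 ± 0.230 and HSPB1 at 0.13 ± 0.253. The list was not tested without MT2A, so how far its calls at 6 h, 24 h and for the mean rest on that gene is open. Kruppel-like factors had a median of 0.07 and a mean of 0.19, with 7 of 9 above 0 and a median above 0 on 5 of 6 arrays (camera, adjusted p = 0.00469, or adjusted p = 0.25 with an estimated correlation). The list was not tested without KLF2 and KLF6. How far its calls at 24 h and for the mean rest on them is open. KLF6 rose by 0.50 ± 0.424 (limma, adjusted p = 0.0496 over the list alone), while KLF2 stood at 0.99 ± 0.705, KLF13 at 0.11 ± 0.20 and KLF7 at -0.10 ± 0.195, and 2 members passed with the block. This call was lost without replicate 1 at 15 h (0.0878) or replicate 2 at 24 h (0.146). The cholesterol list had a median of 0.07 with 16 of 22 above 0 and a median above 0 on 5 of 6 arrays (camera, adjusted p = 5.91e-05, or adjusted p = 0.385 with an estimated correlation, and 0.152 without replicate 2 at 24 h). SQLE stood at 0.40 ± 0.331, HSD17B7 at 0.21 ± 0.170, FDFT1 at 0.16 ± 0.102 (rows at 0.05 and 0.27) and ACAT2 at 0.18 ± 0.143. None passed over the list alone, and 3 did with the block. ER stress genes had a median of 0.01 and a mean of 0.08, with 10 of 19 above 0 and a median above 0 on 3 of 6 arrays (camera, adjusted p = 0.0292, or adjusted p = 0.296 with an estimated correlation). DDIT4 stood at 0.27 ± 0.272, ATF3 at 0.23 ± 0.231, ASNS at 0.16 ± 0.180 and HERPUD1 at 0.10 ± 0.148. The ER stress call was lost with the block (adjusted p = 0.0841) and without replicate 1 or 2 at 6 h (0.159 and 0.141) or replicate 2 at 15 h or 24 h (0.138 and 0.29). The 4 rows of ATF3 had 6-array means from 0.06 to 0.46.

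**Figure D2:**
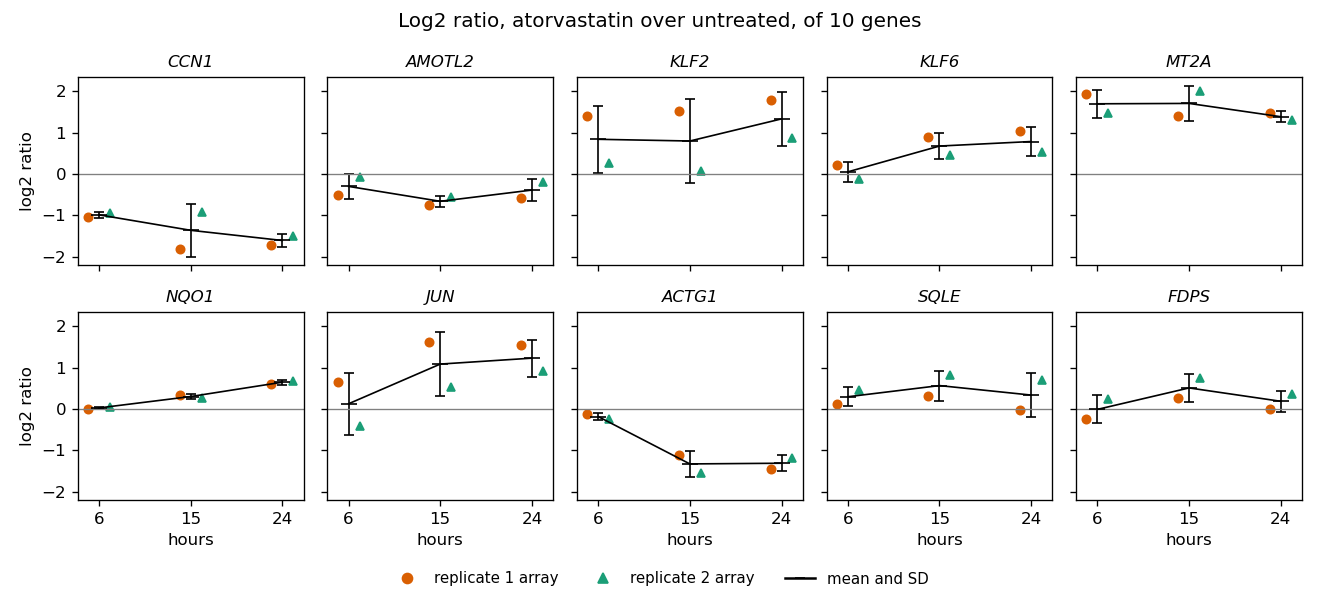
Log2 ratio of atorvastatin over untreated (vertical axis) at 6, 15 and 24 hours (horizontal axis) for 10 genes; circles are replicate 1 arrays, triangles replicate 2 arrays, and black marks the mean and SD of the 2. MT2A lay between 1.30 and 2.01 on the 6 arrays and CCN1 between -1.81 and -0.91.

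Without the replicate block 0 genes passed over all genes for the mean of the 3 times (limma, 163 at an unadjusted p under 0.05), and 8 passed with it (1006 unadjusted). The 8 genes, chosen after their values were seen except where a list names them, were 4 higher and 4 lower. MT2A, KLF2, JUN and TUBA1A stood at 1.60, 0.99, 0.81 and 0.79, with adjusted p of 0.0398, 0.0398, 0.0483 and 0.0416 in the blocked limma fit. MT2A also passed without the block when replicate 1 at 15 h was left out. In that fit 15 h rested on the replicate 2 array alone, which carries 44 spots above 4, so it adds no independent support. ACTA2, CCN1, THBS2 and ENC1 stood at -1.37, -1.32, -0.65 and -0.64, with adjusted p of 0.0398, 0.0398, 0.0483 and 0.0416. Of the 8, JUN (-0.40 on replicate 2), TUBA1A (-0.26 on replicate 1) and ENC1 (0.09 on replicate 2) had the other sign on one 6 h array, while the rule for genes past the threshold asks for one sign on every array. JUN is an AP-1 transcription factor, TUBA1A an alpha tubulin, THBS2 a matrix thrombospondin and ENC1 an actin-binding protein. The count was 0 when replicate 2 at 15 h or either 24 h array was left out, 32 without replicate 1 at 6 h and 46 without replicate 1 at 15 h. Genes of one sign on all 6 arrays numbered 245 (1.69%), where independent signs give 3.125%.

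The ratio fell further between 6 h and 24 h for the SRF and MRTF list, with a median difference of -0.35 and 18 of 19 members lower at 24 h (camera, adjusted p = 7.5e-16, or adjusted p = 0.0656 with an estimated correlation). By fry the list passed as well (adjusted p = 0.0408, and 0.0343 with the block). The median fell on both replicates' arrays, by 0.40 and 0.41. ACTG1 differed by -1.13 (SE 0.233), ACTA2 by -1.70 (SE 0.418), TPM1 by -0.63 (SE 0.184) and TAGLN by -0.86 (SE 0.320). None passed over the list alone in limma, and 7 did with the block. The Kruppel-like factors had a median difference of 0.15 (adjusted p = 0.0901), which passed with the block (adjusted p = 0.0315, or adjusted p = 0.795 with an estimated correlation as well). No gene passed over all genes for 24 h against 6 h (limma, 55 at an unadjusted p under 0.05 and 569 with the block). Nor did any for a difference between any times (35, and 632 with the block).

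The other 18 lists did not pass for the mean of the 3 times in camera. Immediate early genes had a median of -0.03 and a mean of 0.01 (adjusted p = 0.923). In that list JUND stood at 0.39 ± 0.276 and DUSP6 at -0.34 ± 0.482, which with JUN passed over the list alone with the block only. Osteoblast differentiation genes had a median of -0.03 although camera ranked them up (adjusted p = 0.842), with COL1A2 at 0.34 ± 0.207. Extracellular matrix genes stood at 0.04 (0.35), matrix proteases and their inhibitors at 0.001 (0.517) and prenylation enzymes at -0.01 (0.623), medians with adjusted p in parentheses. By the same measures, S phase genes stood at -0.03 (0.203), mitosis genes at 0.02 (0.35), cell cycle inhibitors at 0.01 (0.811) and apoptosis regulators at -0.01 (0.886). Fatty acid synthesis stood at 0.03 (0.517), LXR targets at -0.02 (0.975), ribosomal proteins at 0.07 (0.183), inflammatory cytokines at 0.03 (0.596) and interferon response genes at 0.01 (0.517). With the block only, GADD45A and GADD45B passed over the cell cycle inhibitor list alone, at -0.39 and -0.27, and IL11 over the cytokine list alone, at -0.34. Median and mean had opposite signs for the LXR, cell cycle inhibitor, apoptosis, immediate early and cytokine lists.

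Markers of other cell types, included as a check of the cultures, did not pass either. Leukocyte markers had a median of -0.01 (camera, adjusted p = 0.811), epithelial markers -0.02 (adjusted p = 0.517) and adipocyte and muscle markers -0.001 (adjusted p = 0.768). One of the last, MYH3, an embryonic myosin heavy chain, fell by 0.77 (SD 0.425 over 6 arrays, limma, adjusted p = 0.0262 over the list alone).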

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

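The tests of the SRF and MRTF pattern, of position on the array and of the spots above 4 were chosen after these results were seen; the statement that dye and culture coincide was written before. The SRF and MRTF list differed between 24 h and 6 h in a test of the difference itself (camera, adjusted p = 7.5e-16, or adjusted p = 0.0656 with an estimated correlation and 0.402 with the block as well). Cross-hybridisation among near-identical actins as the whole source is argued against by the list without ACTA2, ACTB, ACTG1 and ACTG2, whose median at 24 h was -0.50 with 15 of 15 below 0 (adjusted p = 1.71e-20, or adjusted p = 0.0471 with an estimated correlation and 0.328 with the block as well). A lower ratio of all abundant transcripts as the whole source is argued against at 24 h by GAPDH at -0.007 and 0.114 and the ribosomal median at -0.074 and 0.152, against -0.512 and -0.635 for the list on the same arrays, gaps beyond the SD of the GAPDH spots and of the ribosomal genes. If the ratios of one orientation were not turned, a dye effect would have one sign on both replicates' arrays, as the list's change from 6 h to 24 h has (-0.402 and -0.407). The other lists' medians changed by at most 0.253 and 0.368 in size on these arrays, less than this list's, but no value excludes a dye effect that differs between times and genes, so that reading and a response of SRF targets to atorvastatin both stay open.

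Several named genes lay above 0 on both arrays of one time and below 0 on both arrays of another. Differences from 6 h to 15 h and from 15 h to 24 h were not tested singly, and none of these genes passed for any difference between times (limma, moderated F, adjusted p = 1 for each). From 6 h to 15 h the means changed by -0.51 for HSPH1, by -0.24 for LSS and by 0.28 for RPL10. From 6 h to 24 h the change was -0.185 for MVK, 0.165 for RPL10 and 0.48 for ATF4, which did not pass the test of that difference (limma, adjusted p = 1 for each). For RPL10 the pattern came from averaging, since at 24 h its 2 rows stood at -0.24 and 0.441 on replicate 1 and at 0.475 and -0.203 on replicate 2. From 15 h to 24 h it was 0.19 for LSS, -0.38 for MVK, 0.54 for DNAJB9 and 0.178 for KLF13. Among list medians, also on opposite sides of 0 on both arrays, fatty acid synthesis changed by 0.085 from 6 h to 24 h (camera, adjusted p = 0.622), LXR targets by -0.222 from 6 h to 15 h, and S phase genes by -0.148 from 6 h to 15 h and by -0.123 from 6 h to 24 h (adjusted p = 0.261).

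The 2 replicates' arrays moved in opposite directions for many genes. A share of this that depends on position on the array fits the tables, since the replicate deviation of neighbouring rows of different genes correlated at 0.288 over 13407 pairs. Some neighbouring rows hold related genes, as those of RPL10 and RPL27 do, and row number was not shown to be array position. The correlation therefore cannot settle whether position is the source. A different response of the 2 cultures cannot be told apart from dye orientation, because both are shared by the arrays of a replicate at every time (lowest correlation of deviations 0.699).

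The replicate 2 array at 15 h had 44 spots above 4. Of these, a share of 0.636 lay next to another in the row numbering, against 0.0032 by chance, which is consistent with a local defect of the array. A response at 15 h is argued against by the other array of that time, where the median at these spots was 0.039.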

How the results depend on the processing

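The fits that left out spots above 4, turned a sign, combined the replicate block with another setting or took the actins out were chosen after the data were examined. Counts of genes at each time, for 24 h against 6 h and for any difference between times stayed at 0 under the replicate block, uncentred values, scaling, quantile normalization, separate rows, a robust prior, array weights and the floor on the ratio. A value on all 6 arrays removed no gene, so the looser filter gives no separate result. For the mean of the 3 times the count of 0 became 8 with the replicate block, 12 with the block and a robust prior, and 11 with the block and spots above 4 left out, each including all 8. Left-out arrays gave 0 to 30 genes at 15 h, 0 to 19 for the mean and 0 to 18 for any difference between times, the highest each time without replicate 1 at 15 h, and 0 at 6 h, 24 h and for 24 h against 6 h. With the sign of the replicate 2 arrays turned, 1284, 876, 779 and 5457 genes passed at 6, 15 and 24 h and for the mean, and 0 list tests. The 8 genes under the block became 0 without the block, 0 with rows tested separately (smallest adjusted p 0.063, 2318 unadjusted) and 0 to 46 with an array left out, and all 8 kept their direction in every such fit. A lone array of a time is there assumed to vary like the others.

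Of the 96 list tests 19 passed. With an estimated correlation 2 did (0 at 6 h and 15 h, 1 at 24 h and 1 for the mean), and by fry 7 (1, 2, 2 and 2). The 7 were SRF at 15 h, 24 h and the mean, and heat shock at each time and the mean. With the block, fry lost only heat shock at 15 h of these (adjusted p = 0.132). Without the block, the estimated correlation was below the preset 0.01 for the SRF (-0.024), heat shock (-0.074), Kruppel-like (-0.054) and ER stress (-0.015) lists. Their calls were thus not lost through a higher correlation. Left-out arrays gave 13 to 19 in all, 0 to 4 at 6 h, 1 to 4 at 15 h and 1 to 5 at 24 h. With SRF 24 h against 6 h counted, 97 of 120 such list results kept direction and call. Leaving out an array of another time leaves a single-time ratio unchanged, so those fits say little about stability. Every single-time call that was lost was lost without an array of its own time. Of the single-time calls, only SRF at 15 h and 24 h held whichever array of its time was left out. The block changed no other list call than those of the YAP list at 6 h, the ER stress list for the mean and the Kruppel-like list for 24 h against 6 h. The adjusted p of the YAP list at 6 h ranged from 0.0378 to 1 and that of ribosomal proteins at 15 h from 0.0188 to 0.825 over left-out arrays, both turning direction without replicate 2. Of 1344 alternatives for 84 named gene values, 1341 kept the direction. Many of these could not turn a sign, so this share is no measure of stability. The block and the robust prior leave a ratio unchanged, as does, for a single time, leaving out an array of another time. In the fit of separate rows, a gene was represented by its row with the smallest p. RPL30 at 15 h ranged from -0.033 to 0.385, CCN2 at 24 h from -0.543 to 0.051 and SRXN1 at 24 h from -0.004 to 0.52 over left-out arrays. The causes were not tested, and without intensities the limit set by signal over background is unknown.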

Other observations

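The family tests below were written before the families' values were seen, while the count of sign patterns and the comparison with the size of the genes seen first were chosen after. Beyond the lists, several genes chosen after their values were seen were low on all 6 arrays. CAV1, the main caveola coat protein, stood at -0.65 ± 0.28 over the 3 times, EPHA2, an ephrin receptor, at -0.57 ± 0.325, and AJAP1 at -0.62 ± 0.429. YWHAH, a 14-3-3 protein, stood at 0.52 ± 0.383, and TUBB2A, a beta tubulin, at 0.45 ± 0.259, above 0 on all 6 arrays. None of these passed over all genes without the block (limma), and AJAP1 and CAV1 passed with the block and either a robust prior or spots above 4 left out.

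Whether the relatives of such genes moved with them was tested without the members that raised the question. The 13 other tubulin genes had a median of 0.03 for the mean of the 3 times, with 8 above 0 and a range of -0.374 to 0.412 (camera, adjusted p = 0.0981 over the 3 families, 0.0654 before adjustment). Among metallothioneins, MT2A at 1.60, MT1G at 0.453 (above 0 on all 6 arrays) and MT1K at 0.378 were left out because they had been seen first. The 6 other metallothionein genes had a median of 0.04 and a range of -0.066 to 0.178 (camera, 0.0498 before adjustment). This may reflect a small shared rise, but the camera value was 0.0981 adjusted over the 3 families, 0.316 with an estimated correlation and 0.132 with the replicate block. The 7 other caveola genes had a median of 0.06, opposite to CAV1, and a range of -0.107 to 0.268 (camera, adjusted p = 0.12, as before adjustment). The median fell short of the nearest gene seen first by 0.422 for tubulins (TUBB2A, SD of the members 0.17) and by 0.334 for metallothioneins (MT1K, SD 0.0921). For caveola genes it fell short by 0.709 (CAV1, SD 0.131). These gaps argue against a shift of the other members of each family by as much as the genes seen first. A camera value of 0.05 or more, or a median on the other side of 0, had been set beforehand as counting against a family shift. The caveola genes met both bounds, which argues against a fall of these 7 genes as a group. Of them 5 lay above 0, while CAV2 and CAVIN1 lay at -0.107 and -0.091, so a small fall of single members is not excluded. Signal over background is unknown, and genes without signal would lie near 0 in either case. The tubulin genes met the first only, which was set aside after the values were seen, because with 8 of 13 above 0 a missed threshold does not show that no smaller rise occurred.

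The 8 genes called with the replicate block were set against the 32 patterns of signs that the 6 arrays can take. The real pattern gave 8 genes and the highest other count, 5306, came from the pattern that follows dye orientation, which shows a structure of the arrays. As that structure was known beforehand, 2 of the 32 patterns had to give as many, and the patterns are too few for a share under 0.05. The other 30 patterns gave 0, with the difference between the replicates, of dye or of culture, left in their residual spread.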
